A study of Mus musculus with 5 samples.

How the data were processed

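Single-cell RNA libraries of marrow cells were made, per the labels, with the 3′ kit of 10x Genomics on a Chromium Chip B. The mice carried a TRAP:tdTomato reporter and had sham surgery or an intracranial injection of SB28 or GL261 cells. Skull pieces were digested with enzymes after the surgery site had been discarded, and a sort removed debris and dead cells, per the labels. File titles also named CD45, a leukocyte marker, and a gate for it was not given in the sources used here. The submitters' processing notes named Cell Ranger, Scanpy and Seurat and the genome build mm10. Versions, gene annotation and cell filters were not given in the sources used here. The deposited values were raw counts of UMIs per gene and cell, with no normalization by the authors, which was checked as whole numbers with totals that differed between cells.

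The 5 tables came in 2 formats. The sham and SB28 skull tables held 32285 genes, of which 40 repeated a name and were summed, and their lowest cell totals were 510 and 500 UMIs. The GL261 skull, SB28 bone marrow and GL261 bone marrow tables held 17560 genes, and their lowest cell totals were 237, 230 and 229 UMIs. No cell in them had a mitochondrial share above 9.98%, against up to 38.1% and 59.4% in the other format. Xist had 50561 and 32875 UMIs in the sham and SB28 skull and 0, 2 and 2 in the other 3 libraries, while the Y gene Ddx3y had 1 and 6 UMIs against 1455, 1855 and 3276, so format and sex of the animals went together. The ribosomal gene Rpl13a was at 978 CPM of all UMIs in the sham skull library and at 73.9 CPM in the GL261 skull library. The formats shared 17023 gene symbols, which held 94.2% of sham skull and 94.7% of SB28 skull UMIs and 98.5%, 98.7% and 98.7% of the others, and only these symbols were compared. In all, 537 genes were in the smaller tables alone and 15222 in the larger tables alone.

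Cells with 200 or more genes and a mitochondrial share of up to 20% were kept, which removed 40 sham skull and 90 SB28 skull barcodes and none elsewhere. Scrublet, run per library through scanpy with an expected rate of 6%, called 75 sham skull, 59 SB28 skull and 157 SB28 bone marrow doublets, which were removed. It called 4 cells of the GL261 skull, 0.109%, and 0 of GL261 bone marrow. A call under 0.5% was taken to mean that the caller has not worked, so no doublets were removed from the GL261 libraries. Of 29702 barcodes 29281 remained. Over all barcodes the median UMIs were 5640.5 in the sham skull, 6570.0 in the SB28 skull, 6931.5 in the GL261 skull, 3355 in SB28 bone marrow and 7318.5 in GL261 bone marrow.

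All libraries were clustered together after scaling to 10000 UMIs per cell and a log transform. The step used 2000 variable genes chosen across libraries, 30 principal components, 15 neighbours and Leiden resolution 1, with seed 0. Variable-region, mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes. No batch correction was applied, since library and group were the same. Clusters were named from fixed markers of 22 cell types. The name was the type with most markers among the 10 leading genes if it had 2 or more there, else the type with the highest mean marker score. At least 3 markers of the type had to be detected, which does not mean enriched. A cluster stayed unnamed if another type had more leading markers, or if depth was low and under 3 own markers led. Clusters 7, 10, 14 and 34 were named with 0 own markers among the leading genes. Of 35 clusters 32 were named, in 15 classes, and 3 stayed unnamed. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene positions came from GENCODE M21 on mm10, an annotation that may differ from that of the authors.

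Shares of cells had exact Clopper-Pearson 95% intervals. Gene levels were UMIs summed over a class and divided by the class total over the shared gene symbols. They had exact Poisson 95% intervals and were given for classes with 50 or more cells in each library. A gene with 0 UMIs was set to a floor of 3, and its fold was given as a bound. Named genes were, in mature neutrophils, monocytes and B cells, those with the 5 largest and 5 smallest ratios against sham, or 3 and 3 between compartments. They needed 50 CPM in either library and separate intervals. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes, sex-linked markers and unnamed transcripts were excluded. Members of 22 fixed gene lists were named where they had the largest ratios of their list, and Acp5 was always named. List medians used members with 20 CPM in either library and were ranked among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Shares of cells with a UMI were also given after thinning cells to 1000 UMIs. The markers, lists, naming rule, comparisons and main settings were fixed before the data were examined.

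Some choices were made later. The lists in the text were limited to mature neutrophils, monocytes, B cells and T cells, and their named members to 2 per list, after a first run over more classes and members gave many reversed values. Osteoclast-like cells were defined by 5 or more UMIs of 5 genes after per-cell values had been seen. Ratios relative to the other cell classes, with 3 genes per side, mature neutrophils as the class lacking Acp5, and the limit of 3000 UMIs were also chosen after seeing the data. Genes named for clusters without a class were chosen after their values were seen. The alternatives fixed in advance were other cell filters, doublets kept, Leiden resolutions 0.5 and 2, thinning before clustering, clustering of each library alone, leukocytes as denominator, size factors, leaving out the 20 most abundant genes, means over cells, expression limits of 5 and 100 CPM and removal of an ambient profile.

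The gene and list steps were tested on simulated Poisson counts around a common mean, which is the counting error that the intervals assume. Variation between cells, animals or batches was not simulated, so the rates are not error rates for these libraries. Of 50 genes with a simulated 2-fold difference, 100% had separate intervals in mature neutrophils for SB28 skull and sham skull, among 2862 genes, and 4.73% of 2662 unchanged genes did. For GL261 skull and sham skull 7.11% of 2475 unchanged genes did, among 2675 genes. In B cells of GL261 skull and GL261 bone marrow the recovered share was 78% of 50 genes at 2-fold and 52% of 50 genes at 0.5-fold, among 4114 genes. In mature neutrophils of each main comparison, all 40 simulated lists with members raised 1.5-fold lay outside the central 95%. Of 40 unchanged lists, 2 did in each SB28 comparison and 4 in each GL261 comparison, among 2862 genes for SB28 skull and sham skull, 2464 for SB28 skull and bone marrow, 2675 for GL261 skull and sham skull and 2516 for GL261 skull and bone marrow. The 2 tumour to sham comparisons share the sham library, so their correlation was simulated 100 times without an effect.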

Results

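The data were droplet single-cell RNA counts from marrow of mice that carried a brain tumour or had sham surgery. SB28 and GL261 are mouse glioma cell lines that were implanted in the brain. Skull marrow came from sham, SB28 and GL261 mice, and bone marrow away from the skull came from SB28 and GL261 mice. Each of the 5 groups had 1 library, so there was no replicate check, and no test across samples was possible. The kept cells numbered 5755 in the sham skull, 4948 in the SB28 skull, 3686 in the GL261 skull, 7678 in SB28 bone marrow and 7214 in GL261 bone marrow. Over all barcodes the libraries held 48382300, 47592729, 31676878, 38411355 and 70178190 unique molecular identifiers (UMIs) in the same order. Intervals are 95% intervals of 1 library each, Clopper-Pearson for shares of cells and Poisson for gene levels, and they cover counting error only. Gene levels are in CPM of the UMIs that a cell class held over the 17023 gene symbols shared by the tables. The sham and SB28 skull tables shared a format that differed from the format of the other 3 tables, so the comparisons within a format were SB28 skull with sham skull and GL261 skull with GL261 bone marrow. The sex of the animals, read from Xist and Ddx3y RNA, went with the format, so comparisons across formats were also between sexes.

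The first question was how the marrow of the skull differed between tumour-bearing and sham mice. In the SB28 skull, neutrophils and their progenitors made up more of the cells than in the sham skull, and B lineage cells made up less. Macrophage-like cells, T cells, basophils and conventional dendritic cells also had larger shares, while erythroid cells had a smaller one. Neutrophils made up 52.2% (50.8 to 53.6) of SB28 skull cells and 29.3% (28.1 to 30.5) of sham skull cells, a log2 ratio of 0.83. B lineage cells made up 17.3% (16.3 to 18.4) in the SB28 skull and 52.6% (51.3 to 53.9) in the sham skull, a log2 ratio of -1.60 (-1.70 to -1.51). T cells were 3.86% (3.34 to 4.43) with SB28 and 1.08% (0.827 to 1.38) in the sham skull, 3.58-fold more. With a finer clustering the T cell log2 ratio was 2.64 in place of 1.84. Granulocyte progenitors were 4.75% with SB28 and 1.81% in sham, a log2 ratio of 1.39. Basophils or mast cells were 2.02% against 0.695%, and conventional dendritic cells were 1.41% against 0.434%. Erythroid cells were 0.404% against 1.69%. Natural killer or innate lymphoid cells were 0.606% against 1.08%, with intervals that overlapped, and cluster 30, which had T cell and innate lymphoid genes and no class name, held 143 SB28 and 8 sham skull cells outside both classes. Monocytes, at 6.51% and 7.09%, did not differ beyond counting error. The sort and the lower UMI limit of each table can set such shares.

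In the GL261 skull the same leading classes differed from sham in the same directions, across the table formats. Neutrophils made up 65.5% (64.0 to 67.1) of GL261 skull cells, a log2 ratio to sham of 1.16. B lineage cells made up 4.75% (4.08 to 5.48), a log2 ratio of -3.47, which was -4.64 among cells with 3000 or more UMIs. Granulocyte progenitors made up 9.41%, 5.21-fold more than in sham. T cells, at 0.895%, did not differ from sham beyond counting error. When each library was clustered alone, no GL261 skull cluster was named T cell, and the log2 ratio of -3.90 used a floor of 3 cells.

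**Figure D1:**
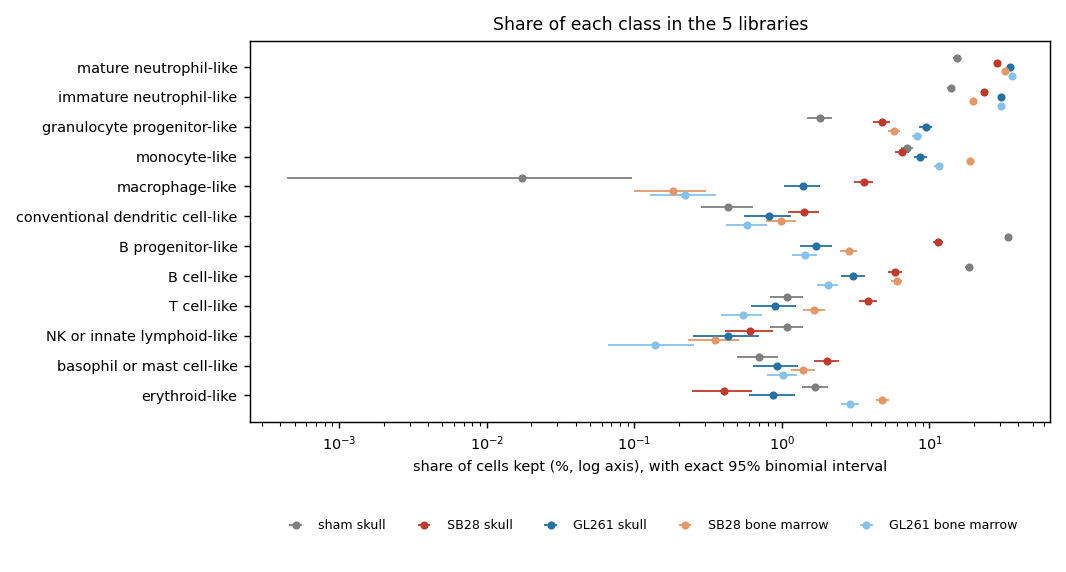
Share of all kept cells (percent, log axis) in 12 cell classes for the 5 libraries, with a point per library and 95% Clopper-Pearson intervals as bars. B progenitors ran from 34.2% in the sham skull to 1.43% in GL261 bone marrow, and B cells from 18.5% to 2.05% in the same libraries. Macrophages ran from 3.58% in the SB28 skull to 0.0174% in the sham skull.

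Mature neutrophils of the SB28 skull had more RNA for secondary granule proteins than those of the sham skull, and less RNA for interferon-induced genes. The higher genes included Cxcl2, a chemokine that draws neutrophils, Cd14, a receptor for bacterial lipopolysaccharide, and Stfa2, an inhibitor of cysteine proteases. Genes at a lower level included Ifi27l2a, an interferon-induced gene, Hrh2, a histamine receptor, and Hist1h1b, a linker histone of dividing cells. Clusters 8 and 12 held most mature neutrophils of both libraries, with 899 and 407 of 1418 cells in the SB28 skull and 354 and 496 of 878 cells in the sham skull. The median log2 ratio over all genes was -0.37 in these cells. Cxcl2 was at 105.0 CPM (97.4 to 113) with SB28 and 13.7 (9.63 to 19.0) in sham, 7.64-fold higher. Cd14 was 13.1-fold higher, Stfa2 was 11.0-fold higher and Cpa6, a carboxypeptidase, was 5.99-fold higher. Cables1, which binds cyclin-dependent kinases, had 2 UMIs in sham and a ratio of 81.5 with a counting interval of 22.4 to 675. Ifi27l2a was at 64.9 CPM (58.9 to 71.4) with SB28 and 278 (258 to 299) in sham, 4.28-fold lower. Hist1h1b was 12.1-fold lower, Prr5l, which binds the mTOR complex, was 5.03-fold lower, Tmem132b was 4.97-fold lower and Hrh2 was 4.50-fold lower. The type I interferon list had 1 member higher and 22 lower, with a median log2 ratio of -0.97 that lay below all 10000 random lists. Inflammatory cytokines and NF-kB targets went both ways, with 7 higher and 6 lower and a median of 0.18, which was -0.21 over members with 100 CPM or more. Among the interferon genes was Rsad2, a virus-inhibiting enzyme, at 27.4 and 80.2 CPM. The secondary granule list had 8 members higher and 2 lower, with a median of 0.82, and Chil3, a chitinase-like protein, was 4.95-fold higher. Of the oxidative phosphorylation genes, 25 were higher and 2 lower, with a median of 0.36. Among immediate early genes, Fos was 2.72-fold higher, and the dissociation and heat shock list had a median of 0.38.

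SB28 skull monocytes carried more RNA for primary granule proteins and glycolytic enzymes, and less for interferon-induced and B lymphoid genes. Socs3, which dampens cytokine signalling, Saa3, an acute-phase protein, Il1r2, a decoy receptor for interleukin 1, and Lrg1, a secreted glycoprotein, were all higher. The B lymphopoiesis list had 0 members higher and 11 lower, and the B lymphoid regulators Ebf1, Ikzf3 and Aff3 were lower, as was Lpl, which releases fatty acids from lipoproteins. Monocyte clusters 3, 9 and 32 made up the class, and cluster 32, marked by Ace, Cx3cr1 and Apoc2, held 13 of 322 SB28 cells and 74 of 408 sham cells. Ifitm1, an interferon-induced membrane protein, was at 419.6 CPM (402 to 438) with SB28 and 4.81 (2.97 to 7.35) in sham, 87.3-fold higher. Saa3 was 63.8-fold higher, Il1r2 was 32.7-fold higher and Lrg1 was 27.5-fold higher. Socs3 had 3 UMIs in sham, and its ratio of 96.1 had a counting interval of 32.6 to 469. Ebf1 was 30.6-fold lower, Ikzf3 was 25.9-fold lower, Aff3 was 19.4-fold lower, Tmcc3 was 15.9-fold lower and Lpl was 12.2-fold lower. The sham monocytes held 169 CPM of Ebf1 and 5938 CPM of Hbb-bs, a haemoglobin gene, and whether these came from free RNA, doublets or misassigned cells was not tested. All 8 measured primary granule genes were higher, with a median log2 ratio of 1.56, and Ms4a3, a marker of granulocyte and monocyte progenitors, was 22.2-fold higher. S100a8, an abundant neutrophil gene, was at 4824 CPM in SB28 and 1152 CPM in sham monocytes. The immunosuppressive myeloid list had 8 members higher and 3 lower, with a median of 0.88. In that list Clec4e, a lectin receptor, was 5.42-fold higher and Il4ra was 3.97-fold higher. Hypoxia and glycolysis genes had a median of 0.77, with Hif1a 2.64-fold and Ldha 2.61-fold higher. The type I interferon list had 2 members higher and 18 lower, with a median of -0.72, and Ifi211 was 2.28-fold lower. MHC class II genes had a median of -0.98, which was 0.38 under the stricter cell filter, and Cd74 was 4.06-fold lower.

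In B cells of the SB28 skull, genes of antigen presentation and oxidative phosphorylation were at a higher level than in the sham skull. Higher genes included Fkbp5 and Tsc22d3, which glucocorticoids induce, Slc8a1, a sodium and calcium exchanger, and Apoe, a lipid carrier. Genes of red cells, among them Alas2, which makes haem, Car2 and Bpgm, were lower. Slc8a1 was at 289.5 CPM (260 to 322) with SB28 and 34.7 CPM in sham, 8.35-fold higher. Fkbp5 was 4.25-fold higher, Apoe was 4.07-fold higher, Tsc22d3 was 3.99-fold higher and S100a6 was 3.89-fold higher. Genes of other cell types were higher in these B cells too, with summed C1q at 10.9 CPM (5.83 to 18.7) and 2.54 CPM (1.39 to 4.26) and S100a8 at 1161 and 647 CPM. Igf2bp3, an RNA-binding protein of early B cells, was 4.73-fold lower. Car2 was 10.1-fold lower, Bpgm was 8.69-fold lower, and Alas2 and Tent5c had 2 and 3 UMIs with SB28, with ratios of 34.9 (9.59 to 290) and 20.2 (6.84 to 98.5). Hbb-bs stood at 183 CPM with SB28 and 10348 CPM in sham B cells, beside these red-cell genes. All 12 MHC class II genes were higher, with a median log2 ratio of 0.99, and H2-DMb1 was 2.68-fold higher. The mix of B cell clusters differed, since cluster 15, which class II genes led, held 54 of 290 SB28 and 92 of 1063 sham B cells. The MHC class I list had 15 members higher and 1 lower, with a median of 0.52, and Psmb8, an immunoproteasome subunit, was 1.89-fold higher. All 30 oxidative phosphorylation genes were higher, with a median of 0.46. Type I interferon genes had 3 members higher and 9 lower, with a median of -0.42, and Herc6 was at 31.1 and 51.3 CPM.

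T cells of the SB28 skull, 191 cells against 62, had more RNA for activation and regulatory genes. The T cell activation list had 14 members higher and 5 lower, with a median log2 ratio of 1.35. Foxp3, the regulator of suppressive T cells, had 125 UMIs with SB28 and 1 in sham, a ratio of 48.8 with a counting interval of 8.59 to 1940. Gzmb, a cytotoxic protease, had 86 UMIs and 1 UMI, a ratio of 33.5 (5.86 to 1340). Genes of the type II interferon response had 12 members higher and 2 lower, with a median of 0.97, and Socs1 was at 114 and 35.8 CPM. Type I interferon genes had 19 members higher and 5 lower, with a median of 0.47, and Zbp1, a sensor of viral nucleic acid, was 3.85-fold higher. All 16 MHC class I genes were higher, with H2-Q7 at 656 and 337 CPM. Neutrophil RNA in these T cells was higher as well, with S100a8 at 3779 and 568 CPM and Ltf at 195 and 10.5 CPM.

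**Figure D2:**
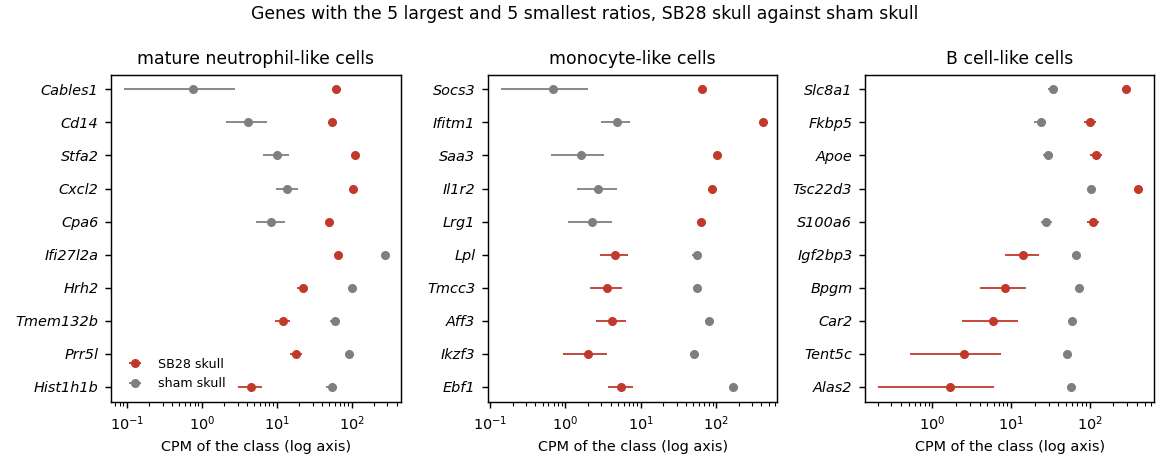
CPM (log axis) of the 5 genes with the largest and the 5 with the smallest ratio in mature neutrophils, monocytes and B cells, SB28 skull in red and sham skull in grey, with 95% Poisson intervals as bars. Ifitm1 in monocytes lay at 419.6 CPM with SB28 and 4.81 CPM in sham, and Ifi27l2a in neutrophils at 64.9 and 278 CPM.

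The series title names bone remodelling and macrophages with ACP5, the tartrate-resistant acid phosphatase that osteoclasts make, so the macrophage-like class and Acp5 were examined in each library. Macrophage-like cells with RNA for the complement genes C1qa, C1qb and C1qc were common in the SB28 skull and nearly lacking in the sham skull. Those of both tumour skulls held Apoe, Spp1, the osteopontin gene, and Mrc1, the mannose receptor gene, all at a higher level per UMI in the GL261 skull, as were Vcam1, Gpnmb and Trem2. This comparison crossed the table formats. The clusters also differed, since cluster 33, with Vcam1 and Mrc1 among its leading genes, held 27 GL261 and 0 SB28 skull cells. Cells of cluster 33 had a median depth of 0.0705 of their library median. The lowest cell total was 237 UMIs in the GL261 and 500 UMIs in the SB28 skull table, so the table limits can set these counts. A difference between the tumours was not tested apart from these. Arg1, an arginase of suppressive myeloid cells, was seen in the SB28 skull and almost not in the GL261 skull. Macrophages made up 3.58% (3.08 to 4.13) of SB28 skull cells, with 177 cells, and 0.0174% of sham cells, with 1 cell, a log2 ratio of 7.69 (4.85 to 10.52). All 177 cells lay in cluster 28, of 214 cells, so that cluster was mostly 1 library, and C1qa, Arg1, Ctsk and Mrc1 were among the genes that set it apart. The GL261 skull had 51 such cells, 1.38% (1.03 to 1.82), of which 27 lay in cluster 33, a cluster of low depth. C1qa reached 1843 CPM (1781 to 1906) in SB28 skull macrophages after osteoclast-like cells were left out, and 42.3% of these 163 cells had a UMI. After thinning to 1000 UMIs per cell the share was 31.6%, against 1.34% and 0.146% of mature neutrophils, which should lack the gene. Median depths were 11192 UMIs in these macrophages and 4752 UMIs in the neutrophils. Arg1 was at 874 CPM (831 to 918), in 30.1% of cells and in 16.5% after thinning, with 0.282% and 0% of neutrophils as background. Trem2, a lipid-sensing receptor, was in 57.7% of cells and in 14.6% after thinning, with 0.494% and 0.0731% of neutrophils. Genes used as microglia markers were also seen, with Tmem119 in 27.6% of SB28 cells and 3.16% after thinning, against 0.141% and 0% of neutrophils. P2ry12 was in 41.7% and 8.86%, against 9.59% and 4.31% of neutrophils, and Sall1 in 3.68% and 1.27%, against 0% of neutrophils. In the SB28 skull cells Apoe was at 5943 CPM, Mrc1 at 509.9 CPM, Spp1 at 484 CPM and Trem2 at 245 CPM. Of these cells 65 had 3 or more C1q UMIs, 35 had 3 or more Arg1 UMIs and 21 had both. GL261 skull macrophages, at a median of 869.5 UMIs, had 5045 CPM (4771 to 5331) of C1qa, 20718 CPM of Apoe, 1240.4 CPM of Mrc1, 1157 CPM of Spp1, 906 CPM of Trem2, 712 CPM of Vcam1, 425 CPM of Gpnmb and 1 UMI of Arg1, and Sall1 was in 13.6% of the 22 thinned cells.

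Acp5 (chromosome 9, 22126727 to 22135711, minus strand, protein coding, mm10) was at 955 CPM (914 to 998) in the SB28 skull macrophage class, with 2023 UMIs. Of the 177 cells, 50 had an Acp5 UMI, 28.2% (21.7 to 35.5), and the share was 11.0% after thinning. Osteoclast-like cells, with 5 or more UMIs over Ctsk, Atp6v0d2, Ocstamp, Dcstamp and Oscar, held nearly all of it. There were 15 such cells in the SB28 skull, 0.303% (0.170 to 0.4995), and the 14 in the class held 1917 of its Acp5 UMIs, 94.8%. Without them Acp5 was at 58.5 CPM (47.9 to 70.7), in 22.7% of cells and in 3.797% after thinning. No such cell was found in the sham skull, where the interval of a count of 0 reached up to 0.0641%, nor in the bone marrow libraries, and the GL261 skull had 1. Cells near the limit, with 2 to 4 UMIs of these genes, numbered 15 in the SB28 skull and 3 in the sham skull. Over the 15 cells the median UMIs were 68 for Ctsk, a collagen-degrading protease (chromosome 3, 95499256 to 95509362, plus strand), 52 for Acp5, 21 for Atp6v0d2 and 18 for Mmp9. In the same cells the median UMIs were 0 for C1q, Arg1, Ly6c2 and Cd79a and 4 for S100a8. GL261 skull macrophages held 253 CPM (196 to 322) of Acp5 from 67 UMIs. The 1 osteoclast-like cell there held 4 of these UMIs, 5.97%. In the other 50 GL261 skull macrophages Acp5 was at 250 CPM (192 to 320), with a UMI in 14 cells, 28%. Most Acp5 of that class thus lay outside osteoclast-like cells. The median depth of these 50 cells was 869.5 UMIs, where a limit of 5 UMIs is harder to reach. Lymphocytes held Acp5 in every library. Acp5 in B cells was at 69.1 CPM in the sham skull, 106.9 in the SB28 skull, 194.9 in the GL261 skull, 284.1 in SB28 bone marrow and 140.9 in GL261 bone marrow. A UMI was in 27.8% of sham and 31.7% of SB28 skull B cells, and in 7.34% and 9.51% after thinning, so B cells could not serve as a class that lacks the gene. Mature neutrophils had a UMI in 0.342% of sham and 0.423% of SB28 skull cells, at median depths of 3006.5 and 4752 UMIs, and in 0% of either after thinning. T cell levels were 114 CPM in the sham skull and 117 CPM in the SB28 skull, which did not differ beyond counting error.

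**Figure D3:**
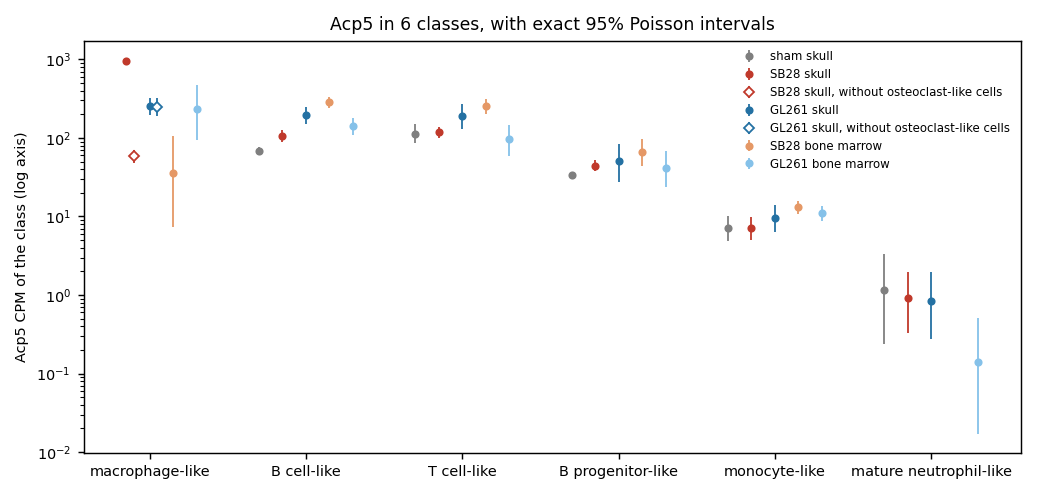
Acp5 level (CPM, log axis) in 6 cell classes of the 5 libraries, with 95% Poisson intervals as bars and open diamonds for macrophages without osteoclast-like cells. The SB28 skull macrophage class lay at 955 CPM with these cells and at 58.5 CPM without them.

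For GL261 skull and sham skull, gene levels were compared across the table formats, and many large ratios were alike in every cell class. Of 25 named genes, 19 differed at least 2-fold the same way in neutrophils, monocytes and B cells, against 9 of 30 for SB28 skull and sham. Rnasek, Rab4b and Tomm6 were lower in GL261 neutrophils by 74.2-fold, 29.9-fold and 22.9-fold, and Il31ra was 29.6-fold higher. Wfdc17, a whey acidic protein of activated myeloid cells, was 48.5-fold higher in neutrophils, at 2979 CPM (2935 to 3023) and 61.5 CPM (52.3 to 71.7). Igfbp6 was 38.9-fold higher, Rftn1 was 36.9-fold higher and Stfa2 was 29.8-fold higher. Thbs1, a matrix glycoprotein, was 76.7-fold lower in neutrophils, at 2.51 and 193 CPM, and Pde2a was 23.2-fold lower. In monocytes Ddah1 was 38.6-fold higher, Lrg1 was 24.7-fold higher, Ifitm1 was 22.9-fold higher, Il31ra was 14.5-fold higher and Cmss1 was 12.2-fold higher. Apoc2 had 0 UMIs in GL261 skull monocytes, at least 119-fold lower than 126 CPM in sham. Ebf1, with 2 UMIs in the GL261 skull, had a sham to GL261 ratio of 239.5 (66.1 to 1981), and Aff3, also with 2, had 114 (31.2 to 942). Rnasek was 75.7-fold lower, and Glcci1, with 3 UMIs, had a ratio of 49.8 (16.8 to 243). B cells had Ddah1 at 79.7-fold, Epo at 45.7-fold, Il31ra at 39.2-fold and Ltf at 29.0-fold higher, and Zbed6, with 0 UMIs in sham, was at least 92.4-fold higher. Ltf is a neutrophil granule gene, and S100a8, another neutrophil gene, was at 1421 CPM in these B cells and 647 CPM in sham B cells. The lower genes of B cells had 1 or 2 UMIs in the GL261 skull, with Mzb1 at a ratio of 71.8 (12.9 to 2840), Cox16 at 40.6 (11.2 to 336), Rnasek at 28.0 (5.01 to 1110), Bpgm at 23.3 (4.15 to 921) and Rbm4 at 20.4 (3.64 to 809).

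Ranked by their ratio relative to the other cell classes, the leading neutrophil genes of the GL261 skull were Rftn1, Steap4, an iron reductase, and Apoe as higher genes and Thbs1, Ctnna3 and Il1rn, the interleukin 1 receptor antagonist, as lower ones. As ratios within neutrophils, not divided by the other classes, Steap4 was 18.8-fold higher and Apoe was 8.63-fold higher, while Ctnna3 was 6.55-fold lower and Il1rn was 4.07-fold lower. Rftn1, Steap4 and Ctnna3 differed the opposite way between SB28 skull and SB28 bone marrow, which also crossed the formats. In monocytes Mt1, a metallothionein, was 10.8-fold higher, and in B cells H2-Aa, an MHC class II chain, was 5.21-fold higher. All 12 MHC class II genes were higher in GL261 skull B cells, with a median log2 ratio of 1.78, and H2-Ab1 was 5.15-fold higher, while cluster 15, led by class II genes, held 38 of 112 GL261 skull B cells and 92 of 1063 sham B cells. All 16 MHC class I genes were higher there too, with a median of 0.99. The secondary granule list was higher in neutrophils, with a median of 1.25 over 9 members, none of them lower, and Ltf, lactoferrin, was 4.70-fold higher. All 7 primary granule genes measured in monocytes were higher, with a median of 1.94, beside S100a8 at 5199 and 1152 CPM and Ltf at 194 and 58.4 CPM. Of the 10 immunosuppressive myeloid genes 8 were higher, with Trem2 3.84-fold and Clec4e 2.77-fold higher. Hypoxia and glycolysis genes had a median of 0.58 in monocytes, with Pkm at 729 and 347 CPM. Type I interferon genes had a median of -0.00 in neutrophils, inside the range of random lists, and 0.79 in B cells. The median over all genes was -0.48 in neutrophils and 0.16 in B cells. Mature neutrophils of the GL261 skull lay mostly in clusters 5, 10 and 11, and those of sham in clusters 8 and 12, and Stfa2 and Wfdc17 were among the leading genes of cluster 10.

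The next question was whether the skull differed from other marrow of mice with the same tumour, although the SB28 pair also differed in sex. In GL261 mice, skull and bone marrow tables had the same format, and the median log2 ratio over all genes was 0.00 in neutrophils. Neutrophils of the skull had more Apoe and more interferon-induced RNA, such as Isg15, a ubiquitin-like protein, and less RNA of the stefin genes. Monocytes of the skull had more glycolysis RNA and less of Cd74 and of late neutrophil genes. Neutrophils made up 65.5% of skull and 66.8% of bone marrow cells, which did not differ beyond counting error, and mature neutrophils lay mostly in clusters 5, 10 and 11 in both. B lineage shares were 4.75% and 3.48%, a log2 ratio of 0.45 (0.18 to 0.72), which was 0.15 with overlapping intervals when each library was clustered alone. The monocyte shares were 8.68% and 11.5%, a log2 ratio of -0.41. Macrophages were 6.24-fold more frequent in the skull, 1.38% against 0.222%, a log2 ratio of 2.64. It was 3.75 among cells with 3000 or more UMIs, which rested on 19 skull and 3 bone marrow macrophages. Among neutrophil genes Apoe was at 296 CPM (283 to 311) in the skull and 109 CPM (104 to 115) in bone marrow, 2.72-fold higher. C1q genes, which mark macrophages, were at 7.38 CPM (5.36 to 9.90) and 1.82 CPM (1.19 to 2.67) in the same neutrophils, and GL261 skull macrophages held 20718 CPM of Apoe. Isg15 was 1.87-fold higher and Fabp5, a fatty acid carrier, was 1.86-fold higher. Stfa3 was 3.06-fold lower, Stfa2 was 2.77-fold lower and Stfa1 was 2.32-fold lower. The type I interferon list had 16 members higher and 7 lower in neutrophils, with a median log2 ratio of 0.21 at percentile 99.98 of the random lists. Iron genes had 6 members higher and 1 lower, with a median of 0.33, and Trf, transferrin, was at 63.2 and 47.5 CPM. Monocytes had Thbs1 at 1.97-fold, Dmkn at 1.94-fold and Pop5 at 1.76-fold higher, and Cd74 at 2.84-fold, Lipe at 1.97-fold and Ndufa1 at 1.73-fold lower. Hypoxia and glycolysis genes had 12 members higher and 4 lower in monocytes, with a median of 0.20 and Gapdh at 799 and 618 CPM. Tertiary granule genes had 1 member higher and 13 lower, with a median of -0.31 and S100a8 1.58-fold lower, and the NF-kB list had 2 higher and 6 lower, with a median of -0.26. In skull B cells 10 MHC class II genes were higher and 2 lower, with a median of 0.34, and H2-DMa was 1.54-fold higher. Pdrg1 was 4.27-fold higher, Cul4b was 4.19-fold higher, and Abhd6 had 2 UMIs in bone marrow and a ratio of 11.96 (2.81 to 107). Retnlg, Mmp8 and S100a6 were 33.0-fold, 21.4-fold and 18.1-fold lower in skull B cells. Neutrophil RNA in general was lower there, with S100a8 at 1421 CPM in skull and 15217 CPM in bone marrow B cells.

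**Figure D4:**
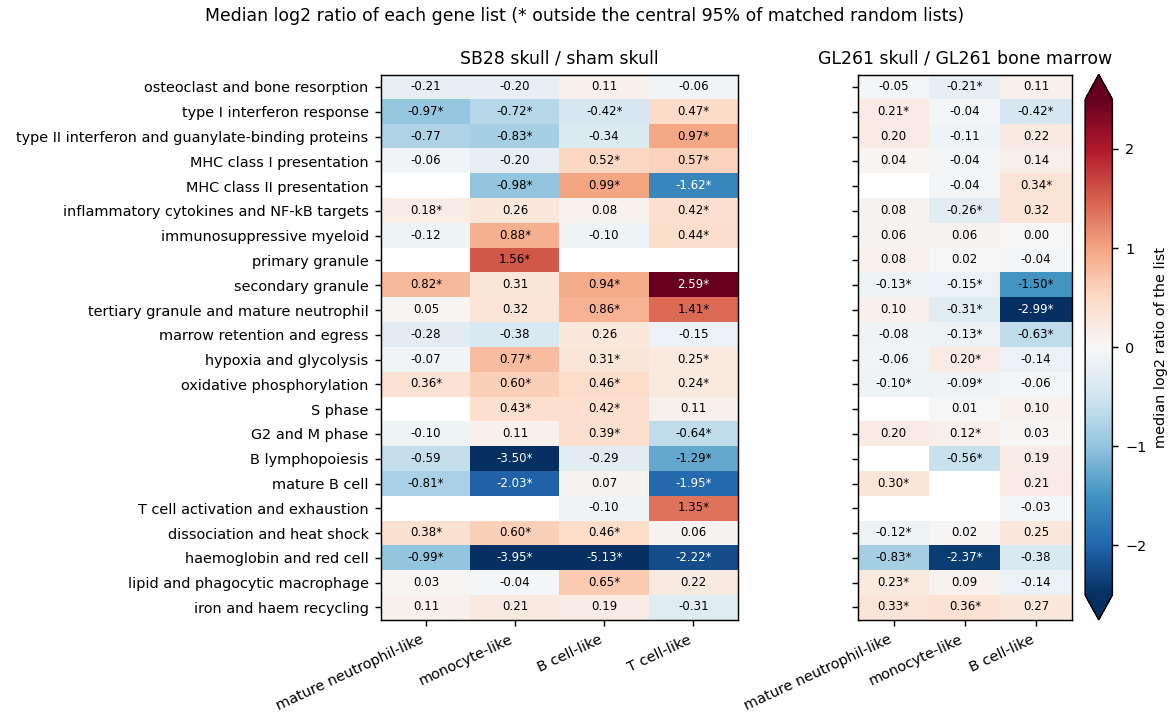
Median log2 ratio of fixed gene lists, drawn as a heat map with lists in rows and cell classes in columns, for SB28 skull over sham skull and for GL261 skull over GL261 bone marrow, with asterisks where the median lay outside the central 95% of random lists. Type I interferon in neutrophils was -0.97 for SB28 skull over sham and 0.21 for GL261 skull over bone marrow.

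In SB28 mice the skull and bone marrow tables had different formats, and by Xist and Ddx3y RNA the animals differed in sex. T cells and B lineage cells made up more of the skull than of bone marrow, monocytes made up less, and neutrophil shares were alike over all kept cells. Skull T cells had more RNA for Tnfrsf9 and Ctla4, receptors of activated and regulatory T cells, and skull B cells had more RNA for early B cell genes such as Il7r and less for class II genes. Neutrophils were 52.2% and 52.3%, but among cells with 3000 or more UMIs their log2 ratio was 0.41, and it was 0.076 with each library clustered alone, both with separate intervals. B lineage cells were 17.3% and 8.82%, a log2 ratio of 0.98 (0.84 to 1.11), which was 3.74 among cells with 3000 or more UMIs, where bone marrow kept 9 of 459 B cells. T cells were 3.86% and 1.65%, a log2 ratio of 1.22, which was 3.15 among those deeper cells. Monocytes were 6.51% and 19.0%, 2.91-fold fewer in the skull, and macrophages were 3.58% and 0.182%. Of 13 named genes, 11 differed at least 2-fold the same way in all 3 classes, against 3 of 18 for the GL261 pair. These included Rnasek, 115-fold higher in neutrophils, Rbm42, 70.3-fold, and Rab4b, 42.1-fold, and, as lower genes, Il31ra, 31.3-fold, and Gphn, 29.3-fold. Rftn1 was 50.2-fold lower in neutrophils. In monocytes Apoc2 had 0 UMIs in bone marrow and was at least 324-fold higher in the skull, Ube2v1, with 2 UMIs, had a ratio of 232 (63.7 to 1926), and Atp5g2 was 76.3-fold higher. Ddah1 was 40.6-fold lower, Il31ra was 19.4-fold lower and Gphn was 10.4-fold lower in monocytes. B cells of the skull had Mzb1, a chaperone of antibody-making cells, at least 51.9-fold higher, and Tomm6 and Rab4b, with 1 UMI each in bone marrow, at ratios of 76.4 (13.5 to 3036) and 61.5 (10.8 to 2449). Outside B cells the median log2 ratio of Mzb1 over the other cell classes was 3.66. Outside monocytes it was 4.15 for Apoc2 and 5.67 for Ube2v1, so these genes were higher in other classes too. Il31ra was 44.7-fold and Ddah1 was 38.5-fold lower in B cells, and Alas2 had 2 skull UMIs and a ratio of 41.0 (10.7 to 349), beside Hbb-bs at 183 CPM in skull and 11688 CPM in bone marrow B cells.

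Ranked by their ratio relative to the other classes, the leading genes of SB28 skull neutrophils were Filip1l, Cpa6 and Ctnna3 as higher genes and Rftn1, Steap4 and Egr1, an immediate early gene, as lower ones. As ratios within the class, Filip1l was 23.6-fold higher, Cpa6 was 5.10-fold higher, Steap4 was 10.3-fold lower and Egr1 was 2.66-fold lower. Monocytes had Ifitm1 3.45-fold higher and Abcd2 1.93-fold lower, and B cells had Tifa 8.71-fold higher and Klhl14 2.73-fold higher. All 12 class II genes were lower in skull B cells, with a median log2 ratio of -1.63, and H2-Aa was 3.97-fold lower. Mature B cell genes had 1 member higher and 12 lower, and Fcer2a, the low-affinity receptor for immunoglobulin E, was 4.52-fold lower. B lymphopoiesis genes had 12 members higher and 3 lower, and Il7r was at 361 CPM in skull and 54.2 CPM in bone marrow B cells. Skull B cells lay mostly in cluster 6, with 236 cells against 54 in cluster 15, and bone marrow B cells mostly in cluster 15, with 371 cells against 88. T cell activation genes had 11 members higher and 8 lower, with a median of 0.99, and Tnfrsf9 was 13.1-fold and Ctla4 was 9.13-fold higher. In neutrophils all 4 primary granule genes were lower, with a median of -1.16. Secondary granule genes were lower in monocytes, all 9 of them, with a median of -0.70, and so were 9 of the 11 lipid and phagocytic genes, with Apoe at 467 and 969 CPM. Mature neutrophils of SB28 bone marrow lay mostly in cluster 1, with 1970 of 2508 cells.

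The last comparisons set the tumours side by side. In neutrophils and monocytes, interferon-induced genes were at a higher level with GL261 than with SB28 in both compartments. The NF-kB list had lower medians in neutrophils, and in bone marrow its members went both ways. In bone marrow, within a format, the type I interferon list had 21 members higher and 2 lower in neutrophils, with a median log2 ratio of 0.98, and 21 higher and 1 lower in monocytes, with a median of 1.37. Slfn5, an interferon-induced regulator, was 6.68-fold higher and Rsad2 was 5.97-fold higher in bone marrow neutrophils. Cluster 10, whose leading genes included Ifit1, Rsad2, Rtp4, Ifit3 and Oasl1, held 781 of 2617 GL261 and 108 of 2508 SB28 bone marrow neutrophils, and 345 of 1285 GL261 and 8 of 1418 SB28 skull neutrophils. The skull neutrophil clusters followed the table formats. Clusters 5, 10 and 11 held 9, 3 and 10 sham and 14, 8 and 13 SB28 skull cells. The skull counts of cluster 10 thus cannot be told apart from format. The NF-kB list had a median of -0.74 in bone marrow neutrophils, with 4 members higher and 8 lower. Cluster 1, with Cxcl2 of that list among its leading genes, held 1970 of 2508 SB28 and 32 of 2617 GL261 bone marrow neutrophils. In the skull, across formats, type I interferon medians were 1.09 in neutrophils and 0.80 in monocytes, and the NF-kB median was -0.88 in neutrophils. B lineage cells were 3.48% of GL261 and 8.82% of SB28 bone marrow cells, a log2 ratio of -1.34, which was 0.36 among cells with 3000 or more UMIs. Granulocyte progenitors were 8.23% and 5.74%, a log2 ratio of 0.52, which was -0.01 under the finer clustering.

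Correlations across genes of skull over bone marrow ratios in SB28 and GL261 mice were weak. The SB28 ratios crossed the table formats and the sexes, and the GL261 ratios did not. A weak value thus cannot tell whether the skull differed alike in mice with either tumour. Genes are not independent replicates, so these values describe the libraries only. Spearman's rho was -0.105 over 4711 genes in mature neutrophils, -0.261 over 4981 genes in immature neutrophils, -0.0920 over 6933 genes in monocytes, -0.000999 over 7591 genes in B cells and 0.148 over 7736 genes in B progenitors. It was 0.175 in monocytes when each library was clustered alone. For tumour over sham ratios, which share the sham library, rho was 0.712 in monocytes against 0.426 simulated with no effect, and the covariance was 0.396 against 0.00988. In B cells rho was 0.428 against 0.0673 simulated, and the covariance was 0.192 against 0.00527. In mature neutrophils rho was 0.654 against 0.672 simulated, and the covariance was 0.310 against 0.0160. The simulated values already include the shared counts of the sham library, and in mature neutrophils rho lay below the simulated value. A deviation of the sham library from other sham mice would also be shared, and it was not tested. Cells with 2 or more UMIs of G2 and M phase genes after thinning made up 38.5% of the sham skull, 42.6% of the SB28 skull, 50.7% of the GL261 skull, 49.9% of SB28 bone marrow and 58.7% of GL261 bone marrow. Before thinning these shares were 80.2%, 83.1%, 87.4%, 74.3% and 94.3%. The SB28 skull thus lay above SB28 bone marrow before thinning and below it after. In immature neutrophils the thinned share was 58.5% in the sham skull, 62.1% in the SB28 skull and 62.9% in the GL261 skull. It was 57.6% in SB28 bone marrow and 71.7% in GL261 bone marrow. Free RNA of dividing cells was not removed from these counts.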

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

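The tests on doublets, osteoclast-like cells, C1q RNA by cell class, B lineage cells outside the neutrophils and table formats were chosen only after the result was seen, and the test at 3000 UMIs after the value at 1000 UMIs was known.

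Macrophage-like cells and osteoclast-like cells set the SB28 skull apart from the sham skull. Osteoclast-like cells were 0.303% of SB28 skull cells and 0 in the sham skull. They held 94.8% of the Acp5 UMIs of the SB28 skull macrophage class, so a small group of cells may set the Acp5 level of that class. In the GL261 skull, 1 such cell held 5.97% of the Acp5 UMIs of the class. Doublets with neutrophils were excluded as the source of the macrophage-like cells of the SB28 skull, since their median share of S100a8 and S100a9 was 0.353% of the neutrophil median. C1q RNA in the other sham cells was 1.63 times the level in the other SB28 skull cells, at 10.2 CPM (9.14 to 11.3) and 6.23 CPM (5.37 to 7.20), but in B cells the order was the other way, at 2.54 and 10.9 CPM, so it was not shown to be free RNA of a common pool. Macrophages that were in the sham suspension and are lacking from its table therefore cannot be told apart from a gain of macrophages with the tumour, with 1 library per group.

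The B lineage share was lower and the neutrophil share was higher in the SB28 skull than in the sham skull. A gain of neutrophils alone was excluded, since among the cells that were not neutrophils the log2 ratio of the B lineage share was -1.04, at 36.3% and 74.5%. For a loss of shallow B lineage cells at the lower UMI limit, a log2 ratio nearer to 0 was predicted among cells with 3000 or more UMIs. It was -1.92, at 15.03% and 56.9%. B lineage cells were shallower in the SB28 skull than in the sham skull, with median UMIs of 4167.5 and 5084 in B cells and 4070.5 and 5750 in B progenitors. The limit of 3000 UMIs thus left out more of the SB28 cells, so this test cannot decide. The sort, the lower UMI limit and the variation between animals stay open as technical explanations, and an effect of the tumour was not tested apart from them.

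Large gene ratios between the GL261 skull and the sham skull may come from the table formats. Of 110 genes with a ratio of 4 or more either way in mature neutrophils, 79.1% differed 2-fold or more the opposite way between SB28 skull and SB28 bone marrow, which also crossed the formats. Among 2212 other genes 2.17% differed as much either way. An effect of the tumour on some of these genes was not tested apart from the formats. Annotation, gene filter and sex of the animals followed the formats and were not tested apart.

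Some lists had medians of opposite sign in SB28 and GL261 mice, and these differences were not tested. In each pair below, 1 ratio crossed the table formats and the other did not, so format and tumour cannot be told apart. In B cells, type I interferon genes had a log2 ratio to sham of -0.42 with SB28 and 0.79 with GL261, a difference of -1.21. For skull against bone marrow the same list had 0.27 and -0.42 in B cells, a difference of 0.69. MHC class II genes in B cells had -1.63 and 0.34, a difference of -1.97. Cluster 15, led by class II genes, held 54 of 290 skull and 371 of 459 bone marrow B cells with SB28. With GL261 it held 38 of 112 and 49 of 148. Tertiary granule genes in B cells had 0.45 and -2.99, a difference of 3.44. That 0.45 was -0.18 as a mean over cells, -1.22 with doublets kept and -1.31 under the stricter filter, so both tumours then had the same sign. In mature neutrophils, haemoglobin genes had 2.0003 and -0.83, a difference of 2.83, and lipid and phagocytic genes had -0.54 and 0.23, a difference of -0.78. G2 and M phase genes in monocytes had -0.36 and 0.12, a difference of -0.48.

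A pair of unnamed clusters had a larger share in the SB28 skull than in the sham skull. Cluster 24 held 0.9499% of SB28 skull and 2.82% of GL261 skull cells and 0.0695% of sham cells. Its GL261 skull cells had a median of 418 UMIs. The lowest cell total was 237 UMIs in the GL261 skull table, against 510 and 500 UMIs in the sham and SB28 skull tables. The table limits can thus set the GL261 share. Cluster 30 held 2.89% of SB28 skull cells, 0.139% of sham cells and 0.0814% of GL261 skull cells.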

How the results depend on the processing

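All alternatives were planned except the limit of 3000 UMIs and the Acp5 level without osteoclast-like cells, which were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Depth limits B cells most, since 9 of 459 SB28 bone marrow B cells had 3000 or more UMIs, and macrophages of the GL261 skull. A class with under 50 cells in a library gave no gene levels under that setting. Of 288 alternative share values, 217 stayed within their interval, 68 moved and 3 reversed. Of 1039 list medians, 781 stayed, 244 moved and 14 reversed, and of 1751 gene ratios, 1510 stayed, 235 moved and 6 reversed. Acp5 values stayed 43 times of 52 and cell cycle differences 16 times of 24, without a reversal. The cell cycle alternatives were all thinned, and shares before thinning were not among them. Except where a reason is given, the cause was not tested.

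Shares are given as log2 ratios. Without a cell filter, B lineage cells had -1.75 for SB28 skull over sham. At Leiden resolution 2 they had -1.72 there and 0.75 for SB28 skull over bone marrow. T cells at that resolution had 2.64 for SB28 skull over sham, 2.84 for SB28 skull over bone marrow and 1.68 for GL261 skull over bone marrow, and granulocyte progenitors reversed to -0.010 for GL261 over SB28 bone marrow. Under the stricter filter, T cells had 2.39 for SB28 over sham and 1.95 over bone marrow, where neutrophils had 0.049, and GL261 macrophages had 3.47 over bone marrow. With thinning before clustering, T cells had 2.44 for SB28 over sham and 2.04 over bone marrow, B lineage cells had 1.17 over bone marrow, and neutrophils had 1.28 for GL261 over sham. Clustered alone, the GL261 skull had -3.25 for B lineage and -3.90 for T cells over sham, and 0.028 for neutrophils, 0.15 for B lineage, with intervals that then overlapped, and -3.09 for T cells over bone marrow, the T cell values because no cluster was named T cell. In SB28 mice, skull over bone marrow then had 0.076 for neutrophils and 0.73 for B lineage. With leukocytes as denominator that neutrophil value was -0.067. Among cells with 3000 or more UMIs, neutrophils had 1.20 and B lineage -1.92 for SB28 over sham, and 1.54 and -4.64 for GL261 over sham. For SB28 skull over bone marrow these deeper cells had 0.41 for neutrophils, 3.74 for B lineage and 3.15 for T cells. GL261 macrophages had 3.75 for skull over bone marrow, from 19 and 3 cells. For GL261 over SB28 bone marrow, B lineage reversed to 0.36 and granulocyte progenitors to -0.19, among few deep B cells.

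The reversed list medians and genes were as follows. Under the stricter filter, MHC class II in monocytes had 0.38 for SB28 over sham and 0.15 for GL261 over sham, haemoglobin in T cells 2.33 for SB28 over sham, with Hbb-bt at 2.89 and Hba-a2 at 2.502, and tertiary granules in B cells -1.31 for SB28 skull over bone marrow. With members at 100 CPM or more, MHC class II in monocytes had 0.18 for GL261 over sham and NF-kB targets in neutrophils -0.21 for SB28 over sham. With doublets kept, secondary granules in B cells had -0.036 for SB28 over sham, with Lcn2 at -0.020 and Ngp at -0.43, and over bone marrow tertiary granules had -1.22 and Hmgb2 -0.015. As means over cells, immunosuppressive genes had -0.021 and G2 and M phase genes 0.029 in T cells for SB28 over sham. Over bone marrow these means gave 0.34 for G2 and M phase in T cells and -0.18 for tertiary granules in B cells, and for GL261 monocytes 0.072 for secondary granules, with Camp at 0.15. With ambient RNA removed, tertiary granules in T cells had -0.40 for SB28 over sham.

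Acp5 was in 11.0% of SB28 skull macrophages after thinning to 1000 UMIs, in place of 28.2%, since fewer UMIs per cell were read. Correlations of skull over bone marrow ratios at 100 CPM were -0.176 in neutrophils, -0.378 in immature neutrophils, -0.212 in monocytes and 0.176 in B progenitors. Clustered alone, the libraries gave -0.170 in neutrophils, a reversed 0.175 in monocytes and -0.0599 in B cells. Cell cycle differences in percentage points were 6.82 for SB28 over sham, -5.42 for SB28 skull over bone marrow and -5.93 for GL261 skull over bone marrow with 1 or more UMIs. After thinning to 2000 UMIs they were 8.61 for SB28 over sham, 15.5 for GL261 over sham and -10.45 for SB28 skull over bone marrow.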

Other observations

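The genes of these clusters and the C1q levels by class were read, as tests, only after the result was seen. An unnamed cluster of the SB28 skull had RNA of the gamma delta T cell receptor together with genes of innate lymphoid cells, and its type was not settled by the markers. Cluster 30 held 143 SB28 skull cells, 8 sham skull cells, 3 GL261 skull cells, 5 SB28 bone marrow cells and 2 GL261 bone marrow cells. Its leading genes included Il23r, a cytokine receptor, Rora, Icos and Cxcr6. Tcrg-C1, a constant part of the gamma chain, had a UMI in 76.2% (68.4 to 82.9) of the SB28 skull cells, and in 40.7% after thinning. Trdc, of the delta chain, was in 62.9% and in 46.7% after thinning, and neither gene was seen in mature neutrophils of that library. Cd3e was in 67.1% and 25.9%, and Il7r, an interleukin 7 receptor chain, in 93.7% and 77.0%. Zbtb16, a regulator of innate-like lymphocytes, was in 77.6% and 44.4%, against 5.36% of neutrophils before thinning. Gata3 was in 46.2% and 20.7%, and Il1rl1, the receptor for interleukin 33, in 16.8% and 14.1%. The cytokine gene Il17a was in 13.3% and 5.19%, at 175 CPM (146 to 207), and Cd8a was not seen in the 143 cells. The median depth was 5539 UMIs, against 4752 UMIs in neutrophils.

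Cluster 24 was led by immunoglobulin genes and had low depth, with a median of 1330 UMIs over 47 SB28 skull cells and 418 UMIs over 104 GL261 skull cells. Igkc, a light chain gene, took up 350473 CPM in the SB28 skull cells and 321284 CPM in the GL261 skull cells, with a UMI in 59.6% and 24.0% of them. Against these shares, 20.9% and 14.7% of mature neutrophils had an Igkc UMI, at median depths of 4752 and 4680 UMIs. After thinning, the shares were 58.6% of 29 SB28 skull cells and 76% of 25 GL261 skull cells of the cluster. They were 6.43% and 4.02% in thinned mature neutrophils of the same libraries. The remaining cells of the cluster were too shallow to be thinned, so the thinned shares cover its deeper cells only. Cluster 27 lay mostly in bone marrow, with 98 SB28 and 112 GL261 cells, against 10, 5 and 17 cells in the sham, SB28 and GL261 skulls.

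C1q RNA outside the macrophage class differed between cell classes of the sham skull, and its source was not tested. It was at 75.8 CPM in erythroid cells, 38.7 CPM in monocytes, 12.2 CPM in mature neutrophils and 2.54 CPM in B cells. In the SB28 skull it was at 9.29 CPM in monocytes, 5.72 CPM in mature neutrophils and 10.9 CPM in B cells.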
